A study of Mus musculus with 10 samples.

How the data were processed

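RNA from sorted mouse prostate luminal epithelial cells was measured on Affymetrix ClariomD (MTA-1.0) whole-transcript microarrays, 1 array per sample. Per the series' design text, the mice carried a doxycycline-inducible histone-bound green fluorescent protein under a Hoxb13-driven transactivator. Cells were sorted for that fluorescence, for CD24 and for intermediate CD49f, and cells with CD45, F4/80 or CD11b were left out, per the same text. Per the labels' protocols, all mice drank doxycycline at 2 mg/ml for 1 week, and RNA had an integrity number of at least 9. The 10 arrays fall into 3 groups by their titles: intact (n = 3), castrated (n = 3) and castrated then given testosterone, called regenerated here (n = 4). The labels call the samples of a group biological replicates and do not say whether an array holds 1 animal or a pool, so p-values measure the spread between these samples.

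The deposited table holds log2 values for 72688 rows, made by the authors with RMA in Affymetrix Expression Console per the submitters' processing notes, with versions not given in the sources used here. RMA subtracts background, forces the arrays to a common distribution and summarises the probes of each row, so a change of all transcripts in the same direction would be reduced by it. The genome build is not given in the sources used here, and no coordinates are printed. Row medians per array ran from 4.12 to 4.22, and the highest value was 19.93. Genes such as Spink1 came close to it in intact arrays, so that changes of such genes may be understated. No detection calls were used. The background control rows had a median of 3.03 and a highest value of 6.40. That value came from castrated replicate 3, and the highest in each other array was 4.66 to 5.58, so it is a wide limit. Of the genes tested, 20138 had all 3 group means at or under it, where changes can be compressed. For arrays no sequencing depth exists, and the number of arrays limits the precision.

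Rows were named through the platform annotation supplied with the table, which can be old, and 827 symbols were updated through the gene identifier against an NCBI RefSeq table of GRCm38.p6, used for names only. Of 65956 non-control rows, 30604 had 1 gene symbol, 2146 had several and were left out, and 33206 had no listed symbol. For 355 genes with several rows the row with the highest mean over all 10 arrays was used, which left 30142 genes. No column of the table was left unused. Of 568 entries in the gene lists, 503 were measured under a single symbol, and the others are not analysed here.

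Each gene was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend) over all 10 arrays in a single model with the 3 groups, no covariate and 7 residual degrees of freedom. The series states that replicates of the groups were compared and names no model. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over the 30142 genes within a contrast, and genes with an adjusted p under 0.05 are called changed. A moderated F-test covered the 3 groups together. The 3 contrasts were castrated against intact, regenerated against castrated and regenerated against intact.

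Before the data were examined, 30 gene lists were fixed: prostate secretory products, androgen response genes, luminal epithelial identity, luminal progenitor genes, markers of basal, neuroendocrine, myeloid, lymphocyte, stromal, endothelial, seminal vesicle, urothelial and erythrocyte cells, cell cycle genes, ER protein folding, amino acid response, sterol and fatty acid synthesis, polyamine and citrate metabolism, oxidative phosphorylation, glutathione and antioxidant genes, interferon response, MHC class I, MHC class II, chemokines, NF-kB targets, apoptosis regulators, immediate early genes, steroid receptors and metabolism, growth factor ligands, and the Wnt and Notch pathway. Each was tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 30 lists, and again with the correlation estimated per list and with fry, which tests a list alone. Camera compares a list with all other genes.

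Genes are named by a rule fixed before the data were examined: per contrast, the 10 largest changes each way among called genes whose groups of arrays do not overlap, leaving out predicted, non-coding and olfactory or vomeronasal symbols; up to 4 called members with the largest change per list, or the 2 largest where none passed; a fixed set of sort markers and androgen-regulated genes; and genes still called against intact after testosterone. A gene outside the rule is said to be so.

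Castration changes were called reversed where the gene was also called, with the opposite sign, between regenerated and castrated arrays. Both contrasts hold the same castrated arrays, so 20 simulations of unchanged groups sharing those arrays gave the values that the sharing alone produces. The scripts were first tested on simulated data with 100 genes shifted by each of 2 sizes: for castrated against intact, 35 of 100 genes shifted by 1 log2 and 96 of 100 shifted by 2 log2 were recovered among 30142 genes with 10 false calls; for regenerated against castrated, 51 and 93 with 6 false calls; for regenerated against intact, 37 and 96 with 10 false calls.

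Alternatives fixed before the data were examined were a fit without the trend, fits on the arrays of 2 groups alone, the replicate number as a block, array weights, quantile normalization again, arrays centred on their medians, only genes above the table's median, every non-control row, the mean of all rows of a gene, a least change of 1 log2, and leaving out each array in turn. Leaving out intact replicate 3 and regenerated replicate 4 together was added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.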

Results

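Gene expression was measured in luminal epithelial cells sorted from mouse prostate by a Hoxb13-driven fluorescent reporter, where Hoxb13 is a homeobox transcription factor of the prostate lineage. Intact mice (n = 3) were compared with mice castrated at 12 weeks of age and left for 6 weeks of regression (n = 3), and with mice then given testosterone for 4 weeks (regenerated, n = 4). Values are log2 RMA intensities, means are given with the SD between arrays, and changes with their standard error from limma. On the first principal component, which held 46.0% of the variance, the 3 castrated arrays lay between 63.7 and 74.5 and the intact arrays between -46.9 and -40.2. Regenerated replicate 4 lay at 2.87 on it, against -30.9 to -22.8 for the other regenerated arrays.

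**Figure D1:**
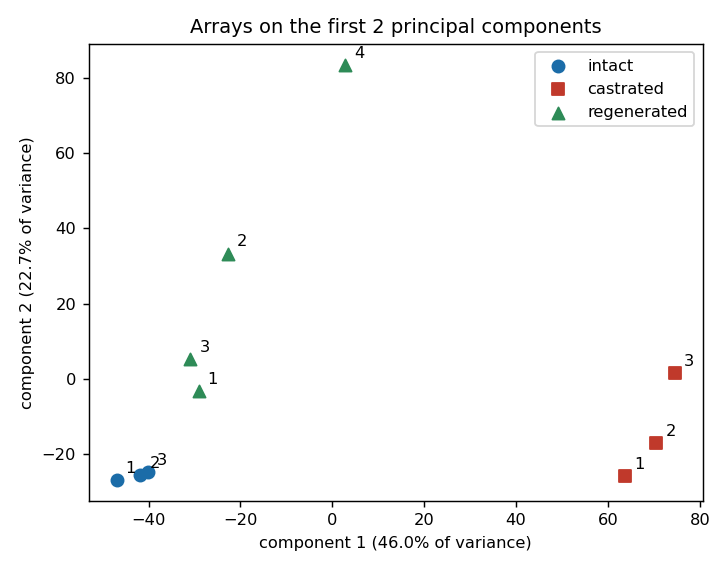
Each point is 1 array, placed by its score on the first (x axis, 46.0% of variance) and second (y axis, 22.7%) principal component of the log2 values, with replicate numbers beside the points. Castrated arrays lie to the right, and regenerated replicate 4 is the highest on the second component, at 83.6.

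The first comparison asks what 6 weeks without testicular androgen did to these cells. Among the genes that fell were some that encode secreted proteins of the prostate. Spink1, a secreted trypsin inhibitor (transcript cluster TC1800001274.mm.1), went from 19.89 ± 0.01 (SD, n = 3) in intact to 7.92 ± 2.09 (n = 3) in castrated arrays. Its intact values lie at the top of the scale, so the change may be understated. Msmb, which encodes beta-microseminoprotein, fell from 17.50 ± 0.44 to 8.25 ± 1.95, and Tgm4, the prostate transglutaminase that cross-links semen proteins, from 16.10 ± 0.18 to 7.42 ± 1.74. Among the genes that rose were Vtcn1, a T cell inhibitory ligand of the B7 family, from 7.07 ± 0.34 to 14.05 ± 0.09, and the chemokine Cxcl15 from 6.49 ± 0.79 to 12.12 ± 1.47. In all, limma with Benjamini-Hochberg adjustment called 2414 of 30142 genes, 1452 higher and 962 lower in castrated arrays, and 1641 of them changed by at least 1 log2. The groups did not overlap in 28.9% of genes, where chance gives 10%.

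The largest fitted rises were in Pnliprp1 and Pnliprp2, both pancreatic lipase-related genes, at 8.35 ± 0.83 (SE) and 8.11 ± 0.85 log2 (limma adjusted p = 0.000353 and 0.000458). They were followed by the lipoxygenase gene Alox12 at 7.57 ± 0.67, Vtcn1 at 6.99 ± 0.29, Gabrp, a subunit of the GABA-A receptor, at 6.64 ± 0.54, and the secreted ribonuclease Rnase1 at 6.44 ± 0.45. Inmt, a methyltransferase, rose by 6.38 ± 0.98, Clca3a2 by 5.94 ± 1.08 and the uroplakin Upk1b by 5.55 ± 0.58. At the other end stood Spink1 at -11.98 ± 0.76 log2 (limma adjusted p = 2.79e-05), the glycosyltransferase Abo at -10.20 ± 0.76, the protease inhibitor Spink5 at -9.76 ± 0.77, Wfdc3 at -9.43 ± 0.60 and the secretoglobins Scgb2b7 and Scgb2b20 at -9.41 ± 1.08 and -9.18 ± 0.98. Timp4, a metalloproteinase inhibitor, and Papss2, which makes the sulfate donor of the cell, fell by 8.51 and 8.24. Pnliprp2, Inmt and Clca3a2 in intact arrays (means from 4.24 to 5.67) and Abo, Spink5, Wfdc3, Scgb2b7 and Scgb2b20 in castrated arrays (4.22, 5.75, 4.68, 3.98 and 5.16) lay under the highest background value of 6.40, so the sizes of these changes and their order depend on the floor. Each of these genes kept its call under every alternative that was followed by gene. Every non-control row and the least change of 1 log2 were not followed in this way.

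Of 15 measured prostate secretory products, 10 fell, none rose and 5 did not pass, and 11 fell with 1 higher when adjusted over the list alone (median -5.39 log2, limma's camera adjusted p = 3.09e-17, and adjusted p = 0.00271 with an estimated correlation). Pbsn, probasin, an androgen-driven secreted protein, was not among them: it was 18.22 ± 0.34 in intact and 17.71 ± 0.26 in castrated arrays (-0.51 log2, limma adjusted p = 0.141). Among 25 androgen response genes, 6 fell and 4 rose, 12 and 5 when adjusted over the list alone (camera adjusted p = 0.0035, and adjusted p = 0.0923 with an estimated correlation). Fkbp5, a co-chaperone of steroid receptors, fell by 2.72 ± 0.39 log2, Odc1, the first enzyme of polyamine synthesis, by 2.32 ± 0.37, and the transporter gene Abcc4 by 2.15 ± 0.37. Of 9 seminal vesicle markers 1 fell (2 when adjusted over the list alone), Spinkl by 3.45 ± 0.42, with a mean of -1.99 and a median of -0.07 (camera adjusted p = 0.00287, and adjusted p = 0.174 with an estimated correlation). Svs2, Svs4 and Svs5 did not pass and varied widely among intact arrays, Svs5 with an SD of 2.47 around 12.47.

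Genes of the secretory route fell along with those of the secreted proteins. Of 30 measured genes of ER protein folding and secretion, 21 fell and none rose, 25 when adjusted over the list alone (median -1.34, limma's camera adjusted p = 6.56e-25, and adjusted p = 0.0434 with an estimated correlation). Kdelr3, a receptor that returns ER proteins from the Golgi, fell by 3.31 ± 0.37 log2, Dnajc3, an ER co-chaperone, by 2.66 ± 0.31 and Herpud1, of ER-associated degradation, by 2.54 ± 0.29. In the amino acid response list 4 of 24 genes fell (5 when adjusted over the list alone) (camera adjusted p = 0.00394, and adjusted p = 0.222 with an estimated correlation). Phgdh, the first enzyme of serine synthesis, fell by 2.79 ± 0.26 and the folate enzyme Mthfd2 by 2.18 ± 0.25. Sterol and fatty acid synthesis had 2 of 22 lower, 4 when adjusted over the list alone, with the desaturase Scd1 at -3.75 ± 0.65 (camera adjusted p = 2.25e-05, and adjusted p = 0.222 with an estimated correlation). For polyamine and citrate metabolism, 2 of 12 fell and 1 rose, 4 and 1 when adjusted over the list alone, with the spermidine synthase Srm at -2.27 ± 0.32 (camera adjusted p = 0.00463, and adjusted p = 0.272 with an estimated correlation). Oxidative phosphorylation had 1 of 23 lower, also when adjusted over the list alone (camera adjusted p = 0.031, and adjusted p = 0.644 with an estimated correlation). That call ended without intact replicate 1 (adjusted p = 0.0684), intact replicate 2 (0.0578), castrated replicate 2 (0.0515) or castrated replicate 3 (0.138).

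Of 27 interferon response genes 13 rose and none fell, 17 when adjusted over the list alone (median 1.14, limma's camera adjusted p = 8.49e-10, and adjusted p = 0.2 with an estimated correlation). Among them were the GTPase gene Igtp at 2.93 ± 0.42 log2, Xaf1 at 2.17 ± 0.30 and Oasl2 at 2.05 ± 0.28. The median of this list was 6.58 in intact replicate 3, against 5.94 and 5.76 in intact replicates 1 and 2 and 7.31 to 7.98 in castrated arrays, and that of the MHC class I list was 7.83 in intact replicate 3, against 7.41 and 7.42. Of 12 MHC class I presentation genes 5 rose, also when adjusted over the list alone (camera adjusted p = 0.000255, and adjusted p = 0.222 with an estimated correlation). Of the immunoproteasome subunits, Psmb10 rose by 3.50 ± 0.34 and Psmb8 by 1.97 ± 0.26. Of 7 MHC class II genes 4 rose, also when adjusted over the list alone, 1 of them H2-Aa at 1.37 ± 0.23 (camera adjusted p = 0.00254, and adjusted p = 0.222 with an estimated correlation). Among 23 chemokines and myeloid growth factors 9 rose and none fell, 10 when adjusted over the list alone (median 0.84, camera adjusted p = 2.27e-07, and adjusted p = 0.174 with an estimated correlation). Cxcl17 rose by 4.57 ± 0.61 and Cxcl16 by 2.31 ± 0.38. NF-kB targets and acute phase genes had 4 of 18 higher, 6 with 1 lower when adjusted over the list alone (camera adjusted p = 0.000528, and adjusted p = 0.24 with an estimated correlation). The interleukin-1 receptor antagonist Il1rn rose by 2.80 ± 0.33 and the adhesion molecule Icam1 by 1.75 ± 0.27. The general leukocyte marker Ptprc, a gate of the sort, was 3.64 ± 0.10 in intact and 3.63 ± 0.09 in castrated arrays, within the range of background rows, and the macrophage marker Adgre1 was 3.76 and 3.81. Another gate gene, Itgam, rose and is given below with the myeloid markers.

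Markers of other cell types were tested as well. Of 17 myeloid markers 2 rose, also when adjusted over the list alone, Itgam, the gene of the CD11b gate, by 0.38 ± 0.08 log2 and the protease gene Ctss by 1.97 ± 0.40 (camera adjusted p = 0.0295, and adjusted p = 0.398 with an estimated correlation). That list lost its call without castrated replicate 1 (adjusted p = 0.12), intact replicate 1 (0.0807) or intact replicate 2 (0.0578), and Ctss lost its own without intact replicate 1 (limma adjusted p = 0.0632) or intact replicate 2 (0.064). None of 10 lymphocyte markers passed limma's test, 2 had an unadjusted p under 0.05, and 1 was higher when adjusted over the list alone. The T cell receptor subunit gene Cd3e was 7.05 ± 1.46 in intact and 10.45 ± 1.91 in castrated arrays (limma adjusted p = 0.0507; list adjusted p = 0.525). Of 13 basal markers 2 rose, also when adjusted over the list alone, keratin Krt17 by 1.31 ± 0.16 (camera adjusted p = 0.0204, and adjusted p = 0.222 with an estimated correlation). The list call was lost without intact replicate 3 (adjusted p = 0.0705). In the urothelial list 2 of 7 rose, 4 when adjusted over the list alone, Upk1b by 5.55 and Upk3a by 5.07 ± 0.63 (camera adjusted p = 0.00314, and adjusted p = 0.0923 with an estimated correlation). The stromal list did not pass (adjusted p = 0.787), with a median of 0.01, a mean of -0.26 and the direction of the test down. Of its 14 genes limma called only Dcn, the proteoglycan decorin, at -4.70 ± 0.61, also when adjusted over the list alone. Endothelial, neuroendocrine and erythrocyte lists did not pass either (camera adjusted p = 0.968, 0.649 and 0.157). Limma called none of their 11, 8 and 2 measured members, of which 1 each had an unadjusted p under 0.05. When adjusted over the list alone, 1 erythrocyte gene, Alas2, was higher, at 1.04 (limma adjusted p = 0.103 over all genes).

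Genes of luminal identity went both ways. Hoxb13, which drives the reporter used for the sort, fell by 2.65 ± 0.42 log2, while Cd24a, whose protein was also used in the sort, rose by 1.72 ± 0.27 and the peptidase gene Dpp4 by 3.09 ± 0.46. The luminal identity list held 5 higher and 2 lower of 12, 6 and 3 when adjusted over the list alone, and did not pass (camera adjusted p = 0.157). Of 17 luminal progenitor genes 6 rose and 1 fell, 9 and 2 when adjusted over the list alone (median 1.45, limma's camera adjusted p = 0.000255, and adjusted p = 0.222 with an estimated correlation). Cd44, a hyaluronan receptor, rose by 4.60 ± 0.54, the urokinase receptor Plaur by 4.21 ± 0.74 and the secreted chaperone clusterin, Clu, by 3.07 ± 0.44, whereas the surface antigen Psca fell by 2.82 ± 0.42.

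Of 20 apoptosis regulators 4 rose, 8 when adjusted over the list alone, among them Casp8 by 1.55 ± 0.27 log2 (camera adjusted p = 0.00949, and adjusted p = 0.222 with an estimated correlation). Immediate early genes, which dissociation can induce, had 2 of 17 higher, 5 when adjusted over the list alone, with Ier3 at 1.01 ± 0.14 (camera adjusted p = 0.00482, and adjusted p = 0.369 with an estimated correlation). The call ended without intact replicate 3 (adjusted p = 0.0534). Growth factor ligands did not pass as a list (camera adjusted p = 0.149), yet 6 of 26 rose and 1 fell, 8 and 2 when adjusted over the list alone: Tgfb2 rose by 4.62 ± 0.34, Hbegf by 1.81 ± 0.32, and Egf fell by 2.12 ± 0.28. The Wnt and Notch list held 5 higher and 1 lower of 23, with the same counts adjusted over the list alone (camera adjusted p = 0.266), among them Axin2, a Wnt target, at 2.00 ± 0.35, Notch1 at 1.99 ± 0.30 and Wnt4 at 1.22 ± 0.20. Steroid receptors and metabolism had 3 higher and 1 lower of 16, also when adjusted over the list alone (camera adjusted p = 0.229), with the estrogen receptor Esr1 up by 1.65 ± 0.24. Glutathione and antioxidant genes had 2 higher and 1 lower of 21, 3 and 2 when adjusted over the list alone. The median was 0.06, the mean -0.15 and the direction of the test up (camera adjusted p = 0.972). Aldh1a1, a retinaldehyde dehydrogenase, fell by 4.28 ± 0.42. Of 22 cell cycle genes 3 rose, also when adjusted over the list alone, with a median of -0.01, a mean of 0.15 and the direction of the test up (camera adjusted p = 0.578). The replication clamp Pcna rose by 1.41 ± 0.25, and the proliferation marker Mki67 was 3.87 ± 0.26 and 3.78 ± 0.19.

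In all, 19 of 30 lists passed camera, 11 up and 8 down, and 2 of them, the secretory products and ER protein folding, passed with an estimated correlation. The count of genes was 1019 without intact replicate 1, 1200 without intact replicate 2, 1473 without castrated replicate 2 and 4258 with array weights.

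**Figure D2:**
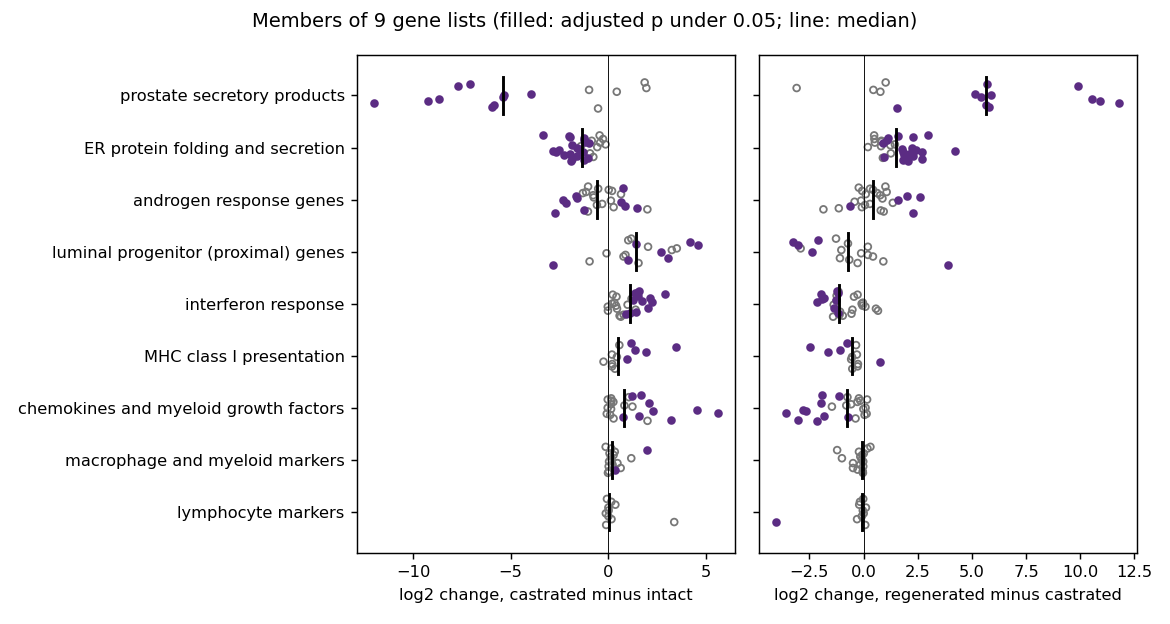
Each point is a member of a gene list, placed by its log2 change between castrated and intact (left) or regenerated and castrated arrays (right). Filled points passed limma's test at an adjusted p under 0.05, and black lines are list medians, -5.39 and 5.66 for the secretory products.

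The second comparison asks how these cells differed after testosterone was given to regressed mice. No group was castrated for the same total time without testosterone. Time since castration, and with it age, thus cannot be told apart from testosterone here. Transcripts of the 3 secreted proteins named first rose. Spink1 reached 19.72 ± 0.18 (SD, n = 4), Msmb 19.16 ± 0.39 and Tgm4 17.98 ± 1.24. These were rises of 11.81, 10.91 and 10.56 log2 over castrated arrays. Spink1 lay at the top of the scale in regenerated arrays as well, so its rise may be understated, and single arrays reached 19.40 for Msmb and Tgm4, close to that limit. Among genes that castration had raised, Pnliprp2 fell from 12.36 ± 2.32 (n = 3) to 4.30 ± 0.33 (n = 4) and the uroplakin gene Upk3a from 9.27 ± 1.73 to 4.13 ± 0.07. Limma with Benjamini-Hochberg adjustment called 1500 genes, 593 higher and 907 lower in regenerated arrays, and 1027 changed by at least 1 log2. Without regenerated replicate 4 the majority turned, with 1076 higher and 1051 lower.

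Of the 15 secretory products 11 rose and none fell, also when adjusted over the list alone (median 5.66, limma's camera adjusted p = 2.31e-23, and adjusted p = 0.000991 with an estimated correlation). Pbsn was among them, at 1.55 ± 0.17 log2 (limma adjusted p = 0.000871). Wfdc3 rose by 9.38 ± 0.56, Abo by 9.36 ± 0.71, Papss2 by 7.31 ± 0.61, Spink5 by 7.18 ± 0.72 and Timp4 by 7.02 ± 0.77, where Wfdc3, Abo and Spink5 were measured against castrated means under the highest background value. Among androgen response genes 4 of 25 rose and 1 fell, 9 and 4 when adjusted over the list alone (camera adjusted p = 0.00127, and adjusted p = 0.0571 with an estimated correlation). Hpgd, which degrades prostaglandins, rose by 2.59 ± 0.28, Fkbp5 by 2.27 ± 0.37 and the zinc finger gene Zbtb16 by 1.99 ± 0.35. Seminal vesicle markers had 1 of 9 higher, also when adjusted over the list alone, Spinkl at 2.99 ± 0.40 (camera adjusted p = 0.0088, and adjusted p = 0.205 with an estimated correlation), and the list call ended without regenerated replicate 4 (adjusted p = 0.0526). Svs5, a seminal vesicle secretory protein gene, was 15.59 in that array and 9.23 on average in the other regenerated arrays.

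ER protein folding rose in 19 of 30 genes, 27 when adjusted over the list alone, with none lower (median 1.51, limma's camera adjusted p = 4e-29, and adjusted p = 0.0282 with an estimated correlation): Sdf2l1 by 4.22 ± 0.56 log2, Kdelr3 by 2.99 ± 0.34, Dnajc3 by 2.72 ± 0.29 and the ER calcium-binding chaperone calreticulin, Calr, by 2.68 ± 0.29. Amino acid response genes had 6 of 24 higher, 11 with 1 lower when adjusted over the list alone (camera adjusted p = 1e-06, and adjusted p = 0.124 with an estimated correlation). Mthfd2 rose by 2.68 ± 0.23 and Phgdh by 2.32 ± 0.24. In sterol and fatty acid synthesis 2 of 22 rose, 3 when adjusted over the list alone (camera adjusted p = 0.000354, and adjusted p = 0.324 with an estimated correlation). Aldh1a1 rose by 4.56 ± 0.39 and Srm by 2.13 ± 0.30, though their lists did not pass (camera adjusted p = 0.951 and 0.0876).

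Interferon response genes fell in 9 of 27, 17 with 1 higher when adjusted over the list alone (median -1.16, limma's camera adjusted p = 2.18e-08, and adjusted p = 0.205 with an estimated correlation). Igtp changed by -1.99 ± 0.39 log2 and Xaf1 by -1.83 ± 0.28. Of 12 MHC class I genes 4 fell and 1 rose, 5 and 1 when adjusted over the list alone (camera adjusted p = 4e-04, and adjusted p = 0.247 with an estimated correlation). Psmb10 fell by 2.47 ± 0.32. MHC class II had 2 of 7 lower, 3 when adjusted over the list alone (camera adjusted p = 0.00409, and adjusted p = 0.247 with an estimated correlation). Chemokines fell in 10 of 23, 11 when adjusted over the list alone (camera adjusted p = 5.7e-08, and adjusted p = 0.17 with an estimated correlation). Cxcl2 fell by 3.03 ± 0.52 and Cxcl16 by 2.64 ± 0.35. NF-kB targets had 5 of 18 lower, 7 when adjusted over the list alone (camera adjusted p = 0.000184, and adjusted p = 0.247 with an estimated correlation). Il1rn fell by 2.48 ± 0.31. Immediate early genes fell in 4 of 17, 10 when adjusted over the list alone (camera adjusted p = 3.04e-07, and adjusted p = 0.205 with an estimated correlation). The nuclear receptor gene Nr4a1 fell by 2.60 ± 0.45 and Klf6 by 2.33 ± 0.28. Ptprc was 3.60 ± 0.03 in regenerated arrays, and limma called no myeloid marker, of which 2 had an unadjusted p under 0.05 (list adjusted p = 0.154).

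Among luminal identity genes 2 of 12 rose and 2 fell, 2 and 7 when adjusted over the list alone (camera adjusted p = 0.154). Keratins Krt8 and Krt18 fell by 2.05 ± 0.32 and 1.69 ± 0.16 log2, and Hoxb13 rose by 1.74 ± 0.39 (limma adjusted p = 0.0321). This Hoxb13 call was lost in 9 of the alternatives, with adjusted p up to 0.105 without castrated replicate 3. Luminal progenitor genes had 4 of 17 lower and 1 higher, 7 and 2 when adjusted over the list alone (camera adjusted p = 0.0222, and adjusted p = 0.379 with an estimated correlation): Cd44 fell by 3.04 ± 0.50, Ly6d by 2.38 ± 0.34, and Psca rose by 3.91 ± 0.39. That list lost its call without castrated replicate 1 (adjusted p = 0.0933) or regenerated replicate 1 (0.124). In the urothelial list 2 of 7 fell, also when adjusted over the list alone (camera adjusted p = 0.0338, and adjusted p = 0.205 with an estimated correlation). The urothelial call was lost without regenerated replicate 3 (adjusted p = 0.064) or 4 (0.0704). Tgfb2 fell by 4.90 ± 0.32, Hbegf by 2.30 ± 0.30 and the Wnt pathway receptor Lgr5 by 0.93 ± 0.09, and Egf rose by 2.02 ± 0.26. The desaturase Fads2 fell by 4.83 ± 0.15 and the gluconeogenic enzyme Fbp1 by 4.74 ± 0.34. Cd3e fell by 4.04 ± 0.87 (limma adjusted p = 0.0253). The Cd3e call was lost without castrated replicate 1 (adjusted p = 0.0886), castrated replicate 2 (0.103), regenerated replicate 2 (0.0751) or regenerated replicate 3 (0.0674).

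The median, mean and test differed in sign for stromal (-0.02, 0.20, down), endothelial (-0.01, 0.05, up), cell cycle (0.07, -0.04, up) and glutathione genes (-0.04, 0.14, up). None of these lists passed camera (adjusted p = 0.889, 0.508, 0.608 and 0.951). Of 30 lists, 14 passed camera, 6 up and 8 down, and 2 passed with an estimated correlation. The count of genes was 816 without castrated replicate 2, 871 without regenerated replicate 2, 934 without regenerated replicate 3 and 822 when only the castrated and regenerated arrays were fitted.

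**Figure D3:**
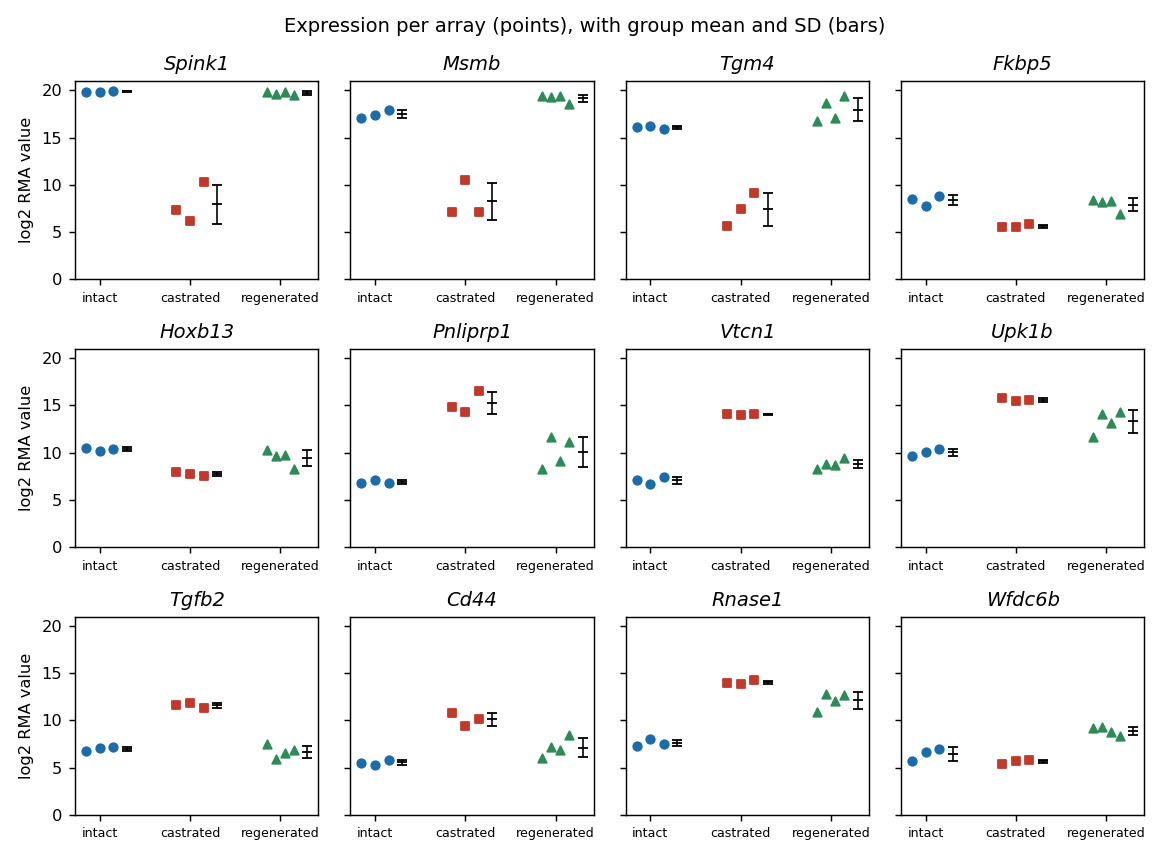
Points are the log2 RMA values of 12 genes in each array, by group, and the bars beside them give the group mean and SD. Spink1, Msmb and Tgm4 are low in castrated arrays alone, whereas Rnase1 is 12.13 in regenerated arrays against 7.59 in intact ones.

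Of the 2414 genes called after castration, 1182 (49.0%) were called in the opposite direction after testosterone: 758 of 1452 that had risen and 424 of 962 that had fallen. Limma called none again with the same sign, nor did any reach an unadjusted p under 0.05 with that sign. The shared castrated arrays push the 2 changes toward opposite signs, so this absence is set in part by construction. In simulated unchanged groups 67.95% of all genes had opposite signs, against 75.16% observed. Independent lists of these lengths would share 43.7 and 18.9 genes. Simulated unchanged groups sharing the castrated arrays gave at most 0. Such groups have few calls in either contrast, so a value near 0 was set by construction, and it leaves out real effects. Across genes, which are not independent replicates, the 2 sets of changes correlated at -0.806, against -0.535 from the shared arrays alone, with a covariance of -0.314 against -0.028. The castrated arrays are too few to be halved, so part of the excess may come from sharing them. In the median gene, 76.7% of a rise and 68.9% of a fall were undone in regenerated arrays. The castrated arrays enter both changes here too, which can shift these shares. The lower share for falls rests on regenerated replicate 4, which kept a median 58.8% of a fall, against 18.0% to 24.2% in the other regenerated arrays. Of a rise, the regenerated arrays kept 22.4% to 24.9%, so a better reversal of rises is not shown. The share reversed was 26.6% where each contrast was fitted on the arrays of its own groups.

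**Figure D4:**
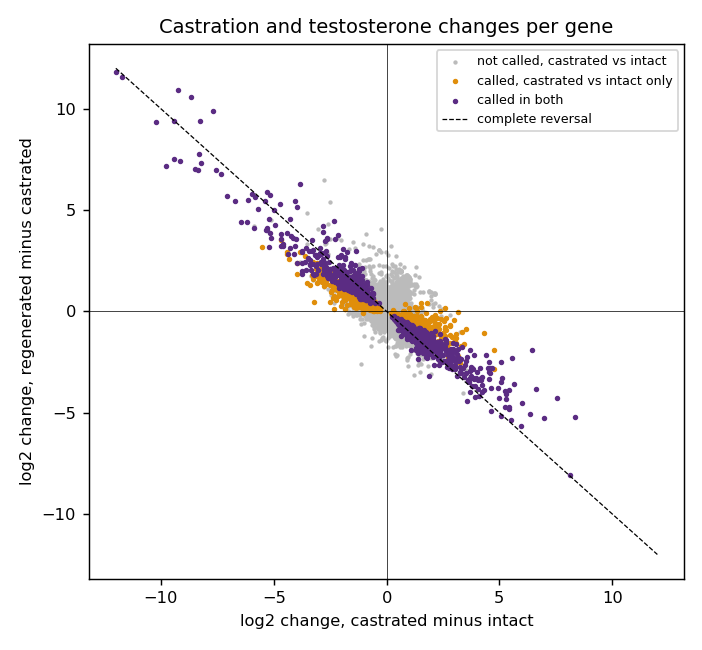
Each point is a gene, with its log2 change between castrated and intact arrays on the x axis and between regenerated and castrated arrays on the y axis. Genes called in both contrasts (purple, 1182) lie near the dashed line of complete reversal, and the shared castrated arrays alone give a correlation of -0.535.

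The third comparison asks what still separated regenerated from intact cells. Rnase1 stayed high, at 12.13 ± 0.89 (SD, n = 4) against 7.59 ± 0.35 (n = 3) in intact arrays, a difference of 4.54 ± 0.42 log2 (limma adjusted p = 0.0173). The protease inhibitor cystatin C, Cst3, and Colca2 were also higher in both castrated and regenerated arrays, by 1.45 ± 0.18 and 2.06 ± 0.25 in the latter, and the inhibitor Spink14 was lower by 1.73 ± 0.20. Wfdc6b, Ccdc80, the histone gene H2bc12 and the B cell scaffold gene Bank1 were higher in regenerated arrays, by 2.43, 2.22, 1.30 and 0.82, and were not called after castration. All 3 group means of Spink14, H2bc12 and Bank1 lay under the highest background value of 6.40, as did the intact mean of Ccdc80, so the sizes of these differences depend on the floor. With Benjamini-Hochberg adjustment limma called 11 genes, 10 higher and 1 lower, and 3019 had an unadjusted p under 0.05. Of genes that castration had lowered, Fkbp5 was 7.91 ± 0.70 against 8.36 ± 0.53 (adjusted p = 0.789) and Hoxb13 9.47 ± 0.86 against 10.39 ± 0.17 (adjusted p = 0.475).

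Luminal progenitor genes were higher as a list (median 0.96, limma's camera adjusted p = 0.00283, and adjusted p = 0.615 with an estimated correlation), with 8 of 17 higher and 1 lower when adjusted over the list alone. Limma called none over all genes, and 10 had an unadjusted p under 0.05. Prom1, a membrane glycoprotein gene, was 8.81 ± 1.41 against 6.56 ± 0.37. Amino acid response genes were also higher (median 0.17, camera adjusted p = 0.042, and adjusted p = 0.615 with an estimated correlation), 2 of 24 when adjusted over the list alone. Immediate early genes were lower (median -0.41, camera adjusted p = 0.00283, and adjusted p = 0.615 with an estimated correlation), 2 lower and 1 higher of 17 when adjusted over the list alone. The median, mean and test differed in sign for luminal identity (-0.12, 0.10, down), androgen response (0.00, 0.02, down), glutathione (0.05, -0.01, up), erythrocyte (0.04, 0.04, down) and Wnt and Notch genes (-0.02, 0.05, up). None of these passed (camera adjusted p = 0.857, 0.962, 0.857, 0.962 and 0.912). None of the 3 lists and none of the 8 genes named here kept its call in every alternative. The count of genes was 0 by limma without intact replicate 1 or 2, castrated replicate 1 or 2, or regenerated replicate 2 or 3, with 1803 to 2963 genes at an unadjusted p under 0.05. It was 6 without castrated replicate 3, 22 (13 higher and 9 lower) without intact replicate 3, 25 without regenerated replicate 4 and 78 without regenerated replicate 1. It was 128, 78 higher and 50 lower, without intact replicate 3 and regenerated replicate 4 together, a setting added after the data were seen.

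Over the 3 groups together, limma's F-test called 1963 genes. The count was 964 without castrated replicate 2 and 2766 without regenerated replicate 4.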

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

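The tests of an unrecorded batch, of leukocytes and of the share of progenitor-type cells, the blend test over all genes at least 1 log2 away and the splits with castrated arrays kept were chosen only after the result was seen, as were the intervals, bootstrap or binomial, set around the values below; the other tests were fixed before their result was seen.

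Among the 4 regenerated arrays, 1 array stood far from the other 3 in 19 of 165 named genes, where chance gives about 1 in 20. Regenerated replicate 4 was that array for 7 genes. It read 18.59 for Msmb against a mean of 19.35 in the others, 6.86 for Fkbp5 against 8.25, 4.24 for the replication helicase gene Mcm6 against 3.83, 6.18 for Ly6d against 5.06, 3.77 for the endothelial gene Plvap against 3.08, 6.38 for Mki67 against 3.71, and 12.93 for the ATP synthase gene Atp5b against 13.53. Regenerated replicate 2 stood apart for Slc4a1 (3.59 against 3.71), Igtp (5.24 against 6.11), Xaf1 (5.92 against 6.62), H2-Aa (4.99 against 4.34), H2-Ab1 (6.42 against 5.49), Tyrobp (4.93 against 3.58) and S100a8 (4.32 against 3.21). Regenerated replicate 1 did so for Herpud1 (16.28 against 15.36), Gstm1 (12.5 against 11.08), Psmb9 (7.50 against 6.91) and Spink14 (4.78 against 4.06), and regenerated replicate 3 for Spinkl (9.06 against 7.25). Of 33206 array rows without a listed gene symbol, limma called 685 between castrated and intact arrays, 463 higher and 222 lower. That is 2.06% of them, against 5.34% of named rows.

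Regenerated replicate 4 stood apart from the other regenerated arrays on the second principal component, and in genes that castration had lowered it kept a median 58.8% of the castration change, against 18.0% to 24.2% in the others, while in genes that castration had raised it kept 22.4%, against 22.4% to 24.9%. A blend of regenerated and castrated-type cells would place genes between those groups. Of all 841 genes at least 1 log2 higher, 35.1% [31.8 to 38.4] lay there, against 39.4% to 53.6% for the other regenerated arrays. Outside lay 546, against at most 255 of 421 in those, which argues weakly against a blend as the whole cause of the higher genes. The margin is narrow, since over 2 times as many was the bound. The larger count outside goes in part with the larger total. Replicates 2 and 3, with 39.4% and 41.6% between, were not far above 35.1%, and the interval treats genes as independent. A blend stays open for the lower genes, of which 55.7% [52.8 to 58.6] lay between. The 27.5% [21.4 to 34.2] of the 200 most deviating genes that lay there does not decide. These are top genes alone, and the share differs by direction (3 of 134 higher and 52 of 66 lower genes). Other cell types in the sort remain open too. The highest median difference of 9 marker lists was 0.242 log2, with an interval of 0.119 to 2.78. In that array Svs5 and Pate4 were 6.36 and 6.73 higher. Pate4, itself on the secretory list, averaged 14.91 in castrated and 12.95 in intact arrays, against 10.14 in the other regenerated arrays. Svs5 averaged 12.47 in intact arrays, against 9.23 in those. Array or RNA quality also remains open: 12 of the 134 higher and 0 of the 66 lower genes carry symbols of small nuclear or nucleolar RNAs (0.272% of genes tested). That count goes by symbol root alone and may be too low. Many of the other higher genes are predicted Gm models, whose RNA type the symbols do not give. Some of these, such as Gm22821, Gm24641 and Gm25484, have the same values. Control rows deviated 1.17 times as much as in the highest other array [0.948 to 1.38], while no biological explanation was tested.

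Intact replicate 3 correlated more with regenerated replicates 1 and 3 (across genes, 0.994 and 0.991) than with intact replicates 1 and 2 (0.99 for both). The test for a mislabelled regenerated sample does not decide. Over 22 genes the median position of intact replicate 3 was 0.541 on a scale from intact to regenerated, with an interval of 0.322 to 0.883. In genes called after castration, it lay a median 7.36% of the way to castrated for rises and 3.82% for falls. The regenerated arrays lay at 22.4% to 24.9% and 18.0% to 58.8%. Those genes were called with this array counted as intact, which draws it toward that group, so they do not decide either. An immediate early response to dissociation also stays open, at -0.216 log2 [-0.586 to -0.0955] against 0.0563 for random lists, while the interferon, MHC class I and MHC class II lists were 0.68, 0.36 and 0.28 higher in this array. For an unrecorded batch, the lower of 2 correlations across genes was 0.158, between the values set for and against it. No biological explanation was tested.

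In castrated arrays 13 of 27 interferon, 5 of 12 MHC class I, 4 of 7 MHC class II and 9 of 23 chemokine genes were higher, and these list calls were lost with an estimated correlation (camera adjusted p = 0.2, 0.222, 0.222 and 0.174). Leukocytes in the sort, which was gated against CD45, F4/80 and CD11b, remain open. The larger median of the myeloid and lymphocyte lists was 0.184 log2 [0.0759 to 0.378] against 1.14 for the interferon list. The medians of both lists, however, lie under the highest background value of 6.40, where changes can be compressed. Only Cd68, Ctss and Cd3e among their members have a group mean above it in intact or castrated arrays. Itgam, the gene of the CD11b gate, was called higher in castrated arrays, with both means under that value. Ctss was higher by 1.97 (limma adjusted p = 0.014, but 0.0632 and 0.064 without intact replicate 1 or 2), Cd3e was 7.05 in intact and 10.45 in castrated arrays (limma adjusted p = 0.0507), and the myeloid list passed camera (adjusted p = 0.0295, and adjusted p = 0.398 with an estimated correlation), but not without castrated replicate 1 (0.12), intact replicate 1 (0.0807) or intact replicate 2 (0.0578). A larger share of progenitor-type luminal cells in the castrated sort may contribute: the luminal progenitor list was higher by a median of 1.45 (camera adjusted p = 0.000255, and adjusted p = 0.222 with an estimated correlation), and arrays of pooled cells cannot part a change in each cell from a change in shares. A response of the cells to castration is the biological explanation the design gives, and it stays open.

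Other splits of the arrays bear on chance. For castrated against intact arrays there are too few splits, 10, for a share under 0.05: fitted on these arrays alone, the real split called 2608 genes and 19 lists, against at most 0 and 8 in the others, each with 1 split as large. For regenerated against castrated arrays, 1 of 35 splits gave as many genes (822, highest other 213), so chance can be excluded, while 2 of 35 gave as many lists (14, highest other 17), so it cannot be excluded for the lists. For regenerated against intact arrays, limma called 0 genes on these arrays alone (2859 at an unadjusted p under 0.05, highest other 8), a count that 35 of 35 splits reach by construction and that decides nothing. With castrated arrays kept, 2 of 35 splits gave at least the 11 genes, so chance cannot be excluded, and the highest other, 36, had regenerated replicate 1 with the intact arrays, which points to a structure among the arrays. For the lists chance cannot be excluded either, with 34 of 35 splits giving at least the 2 lists (highest other 12). Of 100 splits into 3 groups, 2 gave as many genes in the F-test (1963, highest other 2133, where regenerated replicate 1 sat with the intact arrays) and 1 as many reversed changes (1182, highest other 933). By these shares chance can be excluded for both counts. The splits with the highest other counts kept the 3 castrated arrays together as a group. The counts thus show that castrated arrays differ from the rest, and they do not test the parting of intact from regenerated arrays.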

How the results depend on the processing

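Leaving out intact replicate 3 and regenerated replicate 4 together was chosen only after the data were seen. For genes changed, castrated against intact, all alternatives stayed within 1.5 times of 2414 except array weights (4258) and left-out arrays (1019 to 3271). For regenerated against castrated, the count was 822 on the arrays of both groups alone and 816 to 2127 with an array left out; without both doubted arrays 1139 were higher and 1060 lower, a turned majority. The 11 genes of regenerated against intact moved the most: 2 without a trend, 0 on the arrays of both groups alone, 70 with array weights, 1 with quantile normalization again, 1 with arrays centred, 23 above the table's median, 0 over every row (5207 at an unadjusted p under 0.05 by limma), 128 without both doubted arrays, and 0 to 78 with an array left out. The F-test gave 3800 with array weights and 964 to 2766 with an array left out. The share reversed was 26.6% on the arrays of 2 groups alone and 36.2% to 69.2% with an array left out. Lists past the threshold were 2, 2 and 0 with an estimated correlation and, for regenerated against intact, 0 with fry, 6 with array weights, 7 without both doubted arrays and 2 to 6 with an array left out; for the other contrasts, 17 to 19 and 13 to 16. Fewer arrays or genes are part of some settings; otherwise the cause was not tested.

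With the replicate number as a replicate block, regenerated against intact gave 4 genes and 5 lists, and the other counts stayed within 1.5 times, but for regenerated against castrated the majority turned, with 858 genes higher and 779 lower. The numbers do not pair the samples: same-number correlations ran from -0.175 to 0.296, and not every sample correlated best with its own number.

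None of the called genes named here and none of the called lists changed sign. In all alternatives that were followed by gene or list, calls held for 66 of 96, 60 of 83 and 0 of 8 named genes. For lists these counts were 15 of 19, 11 of 14 and 0 of 3. Every non-control row, the least change of 1 log2, fry and the estimated correlation were not followed in this way. With an estimated correlation 2, 2 and 0 lists passed. Another scaling moved the share of higher calls from 60.2% to 52.8% after castration and from 39.5% to 46.4% after testosterone. Changes near background can be compressed, and 20138 genes lie at or under 6.40, a value that background rows reached in castrated replicate 3 alone.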

Other observations

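The gene families below were chosen only after the data were seen, from 239 families of genes sharing a symbol root, and their camera calls are lost with an estimated correlation. Aldehyde dehydrogenases fell after castration in 8 of 20 genes and rose in 2 (median -0.27, limma's camera adjusted p = 0.000233, and adjusted p = 0.884 with an estimated correlation). Aldh3a2, which oxidises fatty aldehydes, fell by 5.19 log2 from 17.20 to 12.01, Aldh1a7 by 4.70 and Aldh6a1 by 4.08. After testosterone 7 rose and 1 fell (camera adjusted p = 0.000219, and adjusted p = 0.944 with an estimated correlation), Aldh3a2 by 3.89 and Aldh1a7 by 5.29. Secretoglobins, small secreted proteins, fell in 10 of 27 after castration (median -1.56, camera adjusted p = 2.71e-10, and adjusted p = 0.884 with an estimated correlation) and rose in 5 after testosterone (camera adjusted p = 4.09e-05, and adjusted p = 0.991 with an estimated correlation). In regenerated against intact arrays their median was -0.52 (camera adjusted p = 3.02e-06, and adjusted p = 0.979 with an estimated correlation), with 0 of 27 called by limma and 8 at an unadjusted p under 0.05. The array median of this family was 4.81 in regenerated replicate 4, against 5.39 to 6.09 in the other regenerated arrays, and 5.76 in intact replicate 3, against 6.84 and 7.05 in the other intact arrays.

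Annexins, which bind membranes in the presence of calcium, rose after castration in 5 of 11 genes (median 0.72, limma's camera adjusted p = 0.00356, and adjusted p = 0.884 with an estimated correlation). Anxa13 rose by 4.17, Anxa3 by 3.33 and Anxa4 by 2.80. Genes with the symbol root of small ribosomal subunit proteins, many of them copies that share sequence, rose in 21 of 88 (median 0.39, camera adjusted p = 1.86e-10, and adjusted p = 0.939 with an estimated correlation). After testosterone 16 of the 88 fell (median -0.44, camera adjusted p = 1.33e-16, and adjusted p = 0.991 with an estimated correlation). Genes with the symbol root Rnu, most of them small nuclear RNAs, had array medians of 10.65 to 14.28 in regenerated arrays, with replicate 4 highest, and 9.45 to 9.79 in intact arrays (median change 2.56, camera adjusted p = 7.96e-12, and adjusted p = 0.979 with an estimated correlation). Castrated arrays had 10.06, 9.66 and 11.27, and castrated replicate 3 lay above regenerated replicate 1. Against castrated arrays the median change was 1.63, with 3 of 14 genes called higher. Rnu3b1, Rnu3b2 and Rnu3b3 had the same values, so the 14 genes are not separate readings. Between regenerated and intact arrays limma called 0 of these 14 genes, and 13 had an unadjusted p under 0.05.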
